A study of Homo sapiens
Mus musculus and Homo sapiens and Mus musculus with 7 samples.

How the data were processed

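RNA was measured in 7 libraries from a mixed culture of HEK293 and NIH3T3 cells, from each line alone, and from IPs with antibodies against the HA or the V5 tag. Per the labels' protocols, the RNA came from standard extracts or IPs, cDNA was made with SMART-seq and libraries with Nextera DNA Flex. Per the labels, each antibody was used in a first and a second IP, and the sample descriptions give lysate numbers that differ between them.

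The deposited files hold whole-number counts of reads per gene. Per the file headers, counts were made with featureCounts 1.5.2 over exons grouped by gene, in paired mode and without strand (option 0), on a combined human and mouse annotation, with the same command for all 7 files. The submitters' processing notes name bcl2fastq, Trim Galore, STAR 2.5.2, SAMtools, featureCounts and hg38. The mouse build and annotation release are not given in the sources used here. Because counting used no strand, reads of genes that overlap cannot be told apart.

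All 58721 human identifiers matched GENCODE 29 in identifier, start and end, and human coordinates are those of hg38. The exonic lengths in the files match the full GENCODE 29 annotation, which was also used for the share of a gene's exonic bases covered by exons of other genes. None of the 54752 mouse identifiers had a symbol in the sources used here, so mouse genes are given by identifier, mouse lists were not tested, and mouse mitochondrial genes were taken by chromosome. GC content and length came from the human reference transcripts.

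The human share of counts was computed per library with exact Clopper-Pearson 95% intervals. HA was compared with V5 by an exact permutation test, two-sided, for which 6 assignments of 2 against 2 libraries allow no p below 0.333. Tests across genes used edgeR 4.0.16 (quasi-likelihood fit and test) in R 4.3.3 on the counts as deposited, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. Over both species, libraries were scaled by total counts with no further factor, since most genes differ by design. Within a species, library sizes were that species' counts with TMM factors, and the fit held both pairs of IPs, the co-culture input and the monoculture of that species. The spread then rested on the 2 pairs of IPs, with 2 residual degrees of freedom, and the single inputs were assumed to vary like the IPs. The biological coefficient of variation was 51.2% for human and 44.8% for mouse genes.

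Gene lists were tested with camera in limma 3.58.1, at a preset correlation of 0.01, with adjustment over 22 lists, and again with an estimated correlation. Single libraries were compared by log2 ratio of CPM with a prior count of 2, among genes with at least 50 CPM in either library, and list medians were placed among 10000 random lists drawn from 20 bins of mean expression. DESeq2 1.42.0 was an alternative. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest. A fold against a group with 0 counts was taken with 3 counts in place of the 0, which leaves out counting error. With 1 to 3 counts the ratio has an exact interval.

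The groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison within a species, up to 8 genes in each direction with the largest fitted change among those called, with a mean of at least 50 CPM and both IPs on the same side. It took 5 genes per species over both species, up to 4 called members of a list, or its 2 most abundant members if none was called, 8 genes per direction in single-library comparisons, and RPL22 and RPL22L1 always. In HA against input, and over all genes of both species, 1 further gene each that met the rule is not reported here. Removal of the GC trend and leaving out the co-culture input were added after seeing the data. The other alternatives were scaling by DESeq2 size factors or by total counts, no filter, a filter of 50 counts in 2 libraries, DESeq2's Wald test, IP order as a block, genes seen in the other line's monoculture left out (over 5% of their level, which kept 6225 of 6244 human and 8212 of 8221 mouse genes), a fit of only the groups compared, and leaving out each IP.

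The procedure was tested on simulated data with 200 changed genes per comparison, made from the real means and library sizes and the spread of the fit. The single inputs were drawn with that same spread. The rates therefore cannot check whether the inputs vary like the IPs. For HA against input, over 5436 genes, it recovered 0% of 2-fold, 8.96% of 4-fold and 42.4% of 16-fold changes, and 10.5% of its calls were unchanged genes. For human genes in HA against V5, over 5492 genes, it recovered 1.49%, 17.9% and 62.1%. For HA against HEK293, over 5432 genes, it recovered 0%, 8.96% and 47.0%. For mouse genes in V5 against input, over 7632 genes, it recovered 0%, 8.96% and 66.7%.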

Results

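RNA was sequenced from a mixed culture of human HEK293 cells, an embryonic kidney line, and mouse NIH3T3 fibroblasts. The human cells carried the ribosomal protein RPL22 with an HA tag, and the mouse cells carried RPL22 with a V5 tag, so that an antibody against either tag could pull down ribosomes of one line with the RNA bound to them. There were 7 libraries: 1 of total RNA from the co-culture (the input), 1 of each line grown alone (the monocultures), 2 HA immunoprecipitates (IPs) and 2 V5 IPs, each pair made up of a first and a second IP. Total gene counts were 1039864 in the co-culture input, 826781 in the HEK293 monoculture and 1999078 in the NIH3T3 monoculture. They were 888270 and 1563389 in the first and second HA IPs, and 2063885 and 1826127 in the first and second V5 IPs. The inputs and monocultures had no replicates, and whether the monocultures carried the tags is not given in the sources used here. Binomial intervals are exact Clopper-Pearson 95% intervals and cover counting error only, since the reads carried no molecular identifiers. The edgeR and permutation p-values measure only the spread between first and second IPs, which edgeR shares in part across genes. Camera p-values at the preset correlation compare list genes with other genes. The IPs were taken to come from the same co-culture. Second IPs were made on lysate numbered after an earlier IP sample, so a pair may not be 2 independent libraries. How the lysates relate is not given in the sources used here.

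The first comparison asked whether each antibody recovered RNA of the line that carried its tag. Human genes held 26.9% of the counts in the co-culture input (26.9 to 27.0%), 79.9% ± 3.22 in the HA IPs (SD, n = 2) and 5.36% ± 1.25 in the V5 IPs (SD, n = 2). Mouse genes held 94.6% ± 1.25 of the counts in the V5 IPs and 20.1% ± 3.22 in the HA IPs. Relative to the input, the odds of a human over a mouse count were 10.9 ± 2.18 times higher in the HA IPs, and the odds of a mouse over a human count were 6.70 ± 1.65 times higher in the V5 IPs. In the monocultures, 0.0131% of the HEK293 counts lay on mouse genes (0.0107 to 0.0158%) and 0.0256% of the NIH3T3 counts lay on human genes (0.0234 to 0.0279%). The human share was 74.5 percentage points higher in HA than in V5 IPs, far more than the spread within either pair. The exact permutation test, two-sided, gave p = 0.333, the smallest that 2 against 2 libraries allow.

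**Figure D1:**
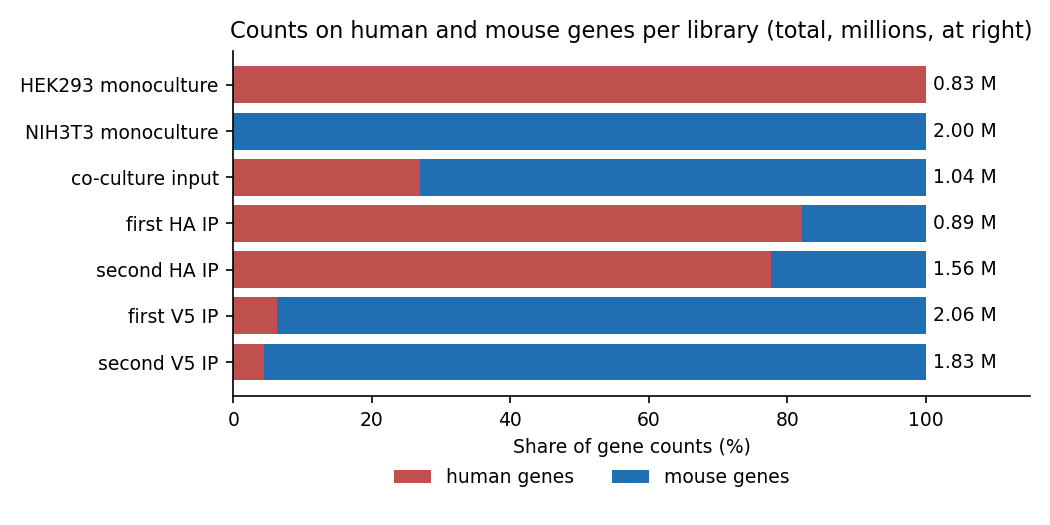
Share of gene counts on human and on mouse genes (percent) in each of the 7 libraries. The HA IPs hold 82.1% and 77.6% human counts and the V5 IPs 6.25% and 4.48%, against 26.9% in the co-culture input.

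Second IPs were set beside first IPs without a test, as 1 library against 1. The human share was 82.1% (82.1 to 82.2%) in the first HA IP and 77.6% (77.5 to 77.7%) in the second. The human share in the V5 IPs was 6.25% (6.21 to 6.28%) in the first and 4.48% (4.45 to 4.51%) in the second. Across genes, which are not independent replicates, log2 CPM (counts per 1e6 counts) of human genes correlated between the HA IPs with Pearson's r = 0.914 and Spearman's rho = 0.871 over 2239 genes. Mouse genes correlated between the V5 IPs with r = 0.957 and rho = 0.932 over 2220 genes. For the species without the matching tag, r was 0.680 for human genes in the V5 pair and 0.797 for mouse genes in the HA pair.

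The gene of the tagged protein was measured in every library. RPL22 (ENSG00000116251.10; hg38 chromosome 1, 6185020 to 6209389), a protein of the large ribosomal subunit, had 33 counts in the co-culture input, 73 in HEK293, 168 and 223 in the HA IPs, 25 and 38 in the V5 IPs and 5 in NIH3T3. As CPM of human counts these were 118 in the input, 88.3 in HEK293, 230 and 184 in the HA IPs and 194 and 465 in the V5 IPs. HA against input gave a log2 difference of 0.62 (SE 0.75), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.887. Its paralogue RPL22L1 (chromosome 3, 170864875 to 170870483) differed by 0.09 (edgeR adjusted p = 0.991). The files do not pair mouse identifiers with symbols, so the mouse Rpl22 and Rpl22l1 genes were not looked up.

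Over all genes of both species, scaled by total counts, nearly every human gene that was called rose in HA relative to V5 IPs, and nearly every mouse gene that was called fell. Of 10936 genes tested, 4784 were higher in HA and 3770 were higher in V5 (edgeR quasi-likelihood test, adjusted p under 0.05). Among 5086 human genes, 4773 were higher in HA, 1 was lower and 312 were not called. Among 5850 mouse genes, 3769 were lower in HA, 11 were higher and 2070 were not called. Of the 11 higher mouse genes 5 were mitochondrially encoded, and the other 6 included ENSMUSG00000043909.16 on chromosome 2 and ENSMUSG00000031955.10 on chromosome 8. The 1 lower human gene was TNR, which also took counts in the NIH3T3 monoculture.

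BCAR1, an adaptor protein of focal adhesions (ENSG00000050820.16; hg38 chromosome 16, 75228187 to 75268053), led the human genes with 158 and 221 counts in the HA IPs and 1 and 0 in the V5 IPs. Its log2 change was 8.90 (SE 0.76; edgeR adjusted p = 8.85e-05), and the CPM ratio was 601 (107 to 23814). FAM92A followed with a ratio of 143.3 (48.5 to 699). The log2 changes were 6.81 for ARL6IP5, an endoplasmic reticulum protein, and 6.52 for KRT18, a keratin of simple epithelia. Their edgeR adjusted p-values were 0.000137 and 0.000459. Exons of other genes covered 29.8% of the exonic bases of FAM92A and 16.3% of those of KRT18, so counts of both are uncertain. In this scaling a human gene rises through the species share alone, since human genes held 79.9% of counts in the HA IPs and 5.36% in the V5 IPs. Within human counts only 3 genes rose in HA over V5, and the ratio of BCAR1 was 54.4. A filter of 50 counts in 2 libraries gave 4459 calls, 4359 of them among the 8554.

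**Figure D2:**
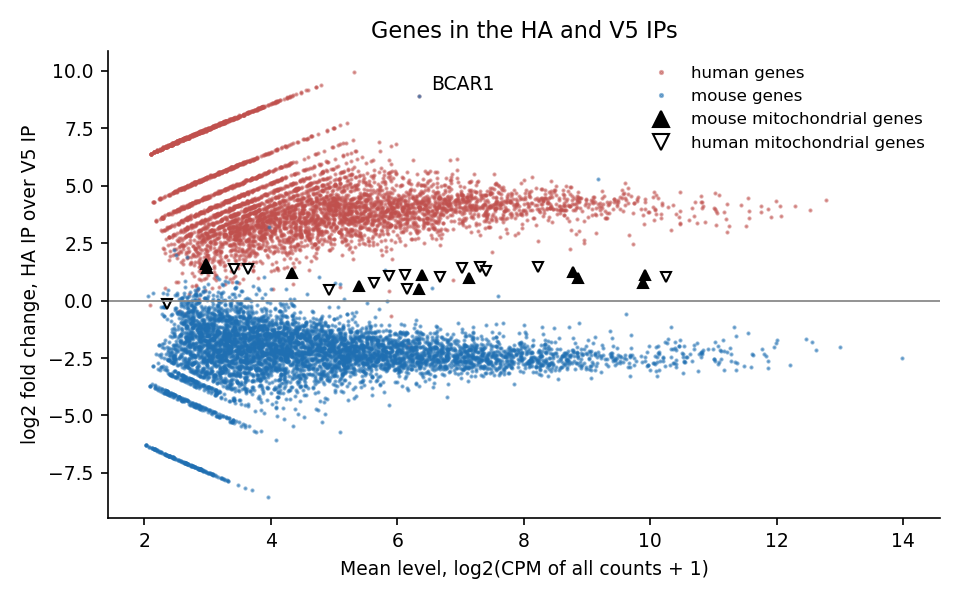
Log2 fold change of HA over V5 IPs against mean level, log2(CPM of all counts + 1), for each tested gene, with mitochondrial genes as triangles. Human genes lie mostly above 0 and mouse genes mostly below it, with 11 mouse genes called higher in HA, of which 5 are mitochondrial.

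The next comparisons were made within each species, so that the species share itself dropped out. RNA made and translated inside mitochondria was low in both kinds of on-target IP. Mitochondrial genes took 5.58% of human counts in the co-culture input and 8.35% in HEK293, but 0.410% ± 0.0794 in the HA IPs (SD, n = 2). They took 1.97% of mouse counts in the input and 2.97% in NIH3T3, but 0.228% ± 0.00877 in the V5 IPs (SD, n = 2). In the species without the matching tag the shares were 2.91% ± 0.890 of human counts in the V5 IPs and 2.12% ± 0.145 of mouse counts in the HA IPs. The difference of HA minus V5 was −2.50 percentage points for human and 1.89 for mouse counts, each with an exact permutation p of 0.333, the smallest possible.

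In human genes, HA IPs against the co-culture input compared RNA on tagged ribosomes with RNA of the whole culture. All 13 measured protein-coding mitochondrial genes fell, with a median log2 change of −3.94. MT-ND4L, a subunit of complex I, was at 9.05 ± 7.13 CPM in the HA IPs (SD, n = 2) and 411 CPM in the input (log2 −5.51, SE 0.80). MT-RNR1, the small mitochondrial ribosomal RNA, was at 44.8 ± 1.80 against 1811 CPM (log2 −5.33, SE 0.58), and MT-ND1 at 117 ± 72.9 against 3716 CPM (log2 −4.98, SE 0.54). The log2 changes of MT-ND3, MT-ND2, MT-ATP8 and MT-ND4 were −5.32, −4.57, −4.19 and −4.16. The edgeR adjusted p-values of these genes ran from 1.10e-16 for MT-ND1 to 4.31e-05 for MT-ATP8. Without the first HA IP, MT-ND3 and MT-ATP8 no longer passed (edgeR adjusted p = 0.116 and 0.174).

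Of the 6244 human genes tested in that comparison, 12 rose and 27 fell, and 15 of the 17 mitochondrial genes were among those that fell. The median log2 change over all genes was 0.38, and changes are to be read relative to it. SNW1, a splicing factor (chromosome 14, 77717599 to 77761207), and PGRMC1, a heme-binding membrane protein (chromosome X, 119236245 to 119244466), had 0 counts in the input. With 3 counts put in place of the 0 in the input library, they were 8.96-fold and 8.74-fold higher in the HA IPs. These folds leave out counting error. The ratio was 18.1 (6.13 to 87.9) for SEC62, part of the endoplasmic reticulum translocon, 16.5 (5.62 to 80.5) for DDX18, an RNA helicase, and 15.5 (5.25 to 75.3) for U2SURP, a splicing factor. DEK, a chromatin protein, was at 378 ± 192 CPM in the HA IPs (SD, n = 2) and 26.0 CPM in the input (log2 3.85, SE 0.95), ZC3H15 differed by 3.83 (SE 1.05), and the nucleolar helicase DDX21 by 3.17 (SE 0.84). Their edgeR adjusted p-values lay between 0.0136 for DEK and 0.0444 for ZC3H15. Across genes the change followed transcript GC content (Spearman's rho = −0.672 over 2237 genes), and with that trend removed none of these 8 genes passed (edgeR adjusted p from 0.0805 for SNW1 to 0.839 for U2SURP). The change shrank for the genes with counts in the input, as for SEC62 from 4.13 (SE 1.05) to 2.88 (SE 1.02) and for DEK to 2.76 (SE 0.90). The fitted values of SNW1 (8.92 to 8.86, SE 2.26 to 2.503) and PGRMC1 (8.94 to 8.85, SE 2.32 to 2.59) hardly moved while their SE grew. With 0 counts in the input the size of their change is not determined, so these values speak neither for nor against that trend. In the HEK293 monoculture SEC62, DDX18, U2SURP and DDX21 were at 275, 237, 282 and 486 CPM, above their 232, 214, 204 and 314 CPM in the HA IPs, so their rise was relative to a low level in the single input library. DEK, ZC3H15, SNW1 and PGRMC1 were at 107, 188, 95.7 and 60.8 CPM in HEK293, below their levels in the HA IPs. Without the first HA IP none of the 8 passed (edgeR adjusted p from 0.0980 for DDX18 to 0.767 for PGRMC1), and without the second only DEK and DDX21 did (the others from 0.0676 for PGRMC1 to 0.360 for ZC3H15). The count of calls, 39, was 140 without the first V5 IP (77 higher and 63 lower) and 137 without the second (75 and 62), which turned the balance.

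Single members of other gene lists also changed between HA IPs and input. EIF2S2, a subunit of translation initiation factor eIF2, rose (log2 3.12, SE 0.71; edgeR adjusted p = 0.00306) and passed in each of 13 alternative settings. The chaperone HSP90AA1 rose (log2 2.79, SE 0.66; edgeR adjusted p = 0.00654), but did not pass with the GC trend removed (log2 2.15, SE 0.60; edgeR adjusted p = 0.0635), without the first V5 IP (0.0518) or without the second (0.0516). The replication helicase subunit MCM5 fell by 2.69 (SE 0.61; edgeR adjusted p = 0.00306, and 0.0687 without the first HA IP). The transcription factor MYC fell by 2.48 (SE 0.66; edgeR adjusted p = 0.0311). With the GC trend removed its change stayed about as large (log2 −2.29, SE 0.63; edgeR adjusted p = 0.0627), and it lost its call without the first (0.334) or the second HA IP (0.219). RPSA, a protein of the small ribosomal subunit, fell by 1.84 (edgeR adjusted p = 0.0304) and lost its call without the first (0.188) or the second V5 IP (0.192).

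Among the 22 gene lists fixed before the data were examined, camera with a preset correlation called 5 in HA against input, all downward. With an estimated correlation no list was called in any of the human comparisons. The mitochondrially encoded list had an adjusted p of 4.73e-33 (0.688 with an estimated correlation), and all 13 members also fell when adjusted over the list alone. Ribosomal proteins had 31 members above 0 and 46 below (adjusted p = 0.0234, and 0.880 with an estimated correlation), with RPSA the 1 called both over all genes and adjusted over the list alone. The snoRNA host genes had 2 above and 11 below and none called either way (adjusted p = 0.0349, and 0.688 with an estimated correlation); SNHG5 differed by −1.09 (edgeR adjusted p = 0.658). The ATF4 stress response had 7 above and 14 below (adjusted p = 0.0234, and 0.688 with an estimated correlation), and 1 gene fell adjusted over the list alone, against none over all genes. Its abundant member PHGDH, an enzyme of serine synthesis, differed by −1.81 (edgeR adjusted p = 0.0926). Glycolysis and hypoxia had 6 above and 10 below (adjusted p = 0.0234, and 0.688 with an estimated correlation), with 2 that fell adjusted over the list alone and a mean of 0.08 opposite in sign to the median of −0.43. With the GC trend removed, neither the ATF4 nor the glycolysis list was called (adjusted p = 0.0854 and 0.116), and the nuclear non-coding list was (0.0022).

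The other lists were not called in HA against input. For translation factors 21 of 32 members lay above 0, and 1 gene, EIF2S2, rose over all genes while 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.444). For heat shock 10 of 13 lay above 0 (adjusted p = 0.096), for ER chaperones and translocon 24 of 32 (0.538), for mitosis 20 of 29 (0.568), for proteasome 20 of 31 (0.737), and for nuclear-encoded oxidative phosphorylation 29 of 48 (0.995). DNA replication had 19 of 28 above 0 and a median of 0.50, while camera pointed down relative to other genes (0.688); 1 member, MCM5, fell over all genes and 2 fell adjusted over the list alone. Adjusted p-values were 0.0837 for nuclear non-coding RNA (1 of 5 above 0), 0.0925 for collagen and matrix (2 of 5), 0.096 for cholesterol synthesis (9 of 21), 0.209 for immediate early genes (4 of 7) and 0.441 for histones (5 of 14). They were 0.671 for the interferon response (6 of 8), 0.688 for HEK293-associated genes (2 of 6), 0.737 for fibroblast markers (3 of 3) and 0.782 both for YAP and TGF-beta targets (3 of 4) and for p53 targets (7 of 9).

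In mouse genes, V5 IPs against the co-culture input put the same question to the NIH3T3 cells. Of 8221 genes tested, 26 rose and 41 fell, and 10 of 12 mitochondrial genes were among those that fell, at a median of 10.3-fold over all 12. The genes that rose included ENSMUSG00000028218.19 on chromosome 4, with a ratio of 20.4 (6.92 to 99.3; edgeR adjusted p = 0.01002), and ENSMUSG00000027091.14, at 342 ± 12.3 CPM in the V5 IPs (SD, n = 2) and 25.6 CPM in the input (log2 3.73, SE 0.61; edgeR adjusted p = 0.00126). The mouse lists were not tested, since mouse identifiers had no symbols. The count of 67 was 1 without the first V5 IP, 1 without the second, 867 without the first HA IP and 854 without the second. Both named genes lost their calls without the first V5 IP (edgeR adjusted p = 0.351 and 0.0998) or the second (0.855 and 0.146).

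Human RNA in the HA IPs was then compared with the human RNA found in the V5 IPs. Mitochondrial transcripts, the myosin heavy chains MYH9 and MYH10 and a few other genes were lower in HA, and BCAR1 was higher. Of 6244 genes, 3 rose and 20 fell (edgeR quasi-likelihood test), and 12 of those that fell were mitochondrial. BCAR1 was at 212 ± 13.5 CPM in the HA IPs (SD, n = 2; log2 5.69, SE 1.22; edgeR adjusted p = 0.00121), a ratio of 54.4 (9.70 to 2153) over V5 IPs. Its call was lost with a filter of 50 counts in 2 libraries (edgeR adjusted p = 0.0712), in DESeq2 (0.150), without the first HA IP (0.144) and without the second (0.698). PCBD1, a pterin dehydratase, differed by 2.73 (SE 0.69; edgeR adjusted p = 0.0238) and lost its call in 10 of 14 settings, among them without the second HA IP (1.00), the first V5 IP (0.0773) and the second V5 IP (0.0841).

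The genes that fell outside mitochondria included CIT, a kinase of cytokinesis, with 1 and 4 counts in the HA IPs and 4 and 40 in the V5 IPs (log2 −6.10, SE 1.10; edgeR adjusted p = 2.99e-05). It lost its call without the first HA IP (0.101) or the second (0.0975). The non-muscle myosin heavy chains MYH9 and MYH10 had log2 changes of −4.23 and −3.00 (edgeR adjusted p = 3.73e-09 and 0.00405). Both lost their calls with a filter of 50 counts in 2 libraries (edgeR adjusted p = 0.116 and 0.119). MYH9 was at 53.5 ± 65.7 CPM in the HA IPs and 986 ± 1017 CPM in the V5 IPs (SD, n = 2 each), and lost its call without the first V5 IP (0.0619), in DESeq2 (0.531) and with the fit limited to these IPs (0.0879). MYH10 lost its call without the second HA IP (1.00) and with the fit limited to these IPs (0.0879). TRIP11, a Golgi protein, fell by 3.23 (SE 0.59; edgeR adjusted p = 2.99e-05) and kept its call in each of 14 settings. TNR, an extracellular matrix protein of the nervous system, fell by 5.50 (SE 0.57; edgeR adjusted p = 3.61e-18), with 160 counts in the NIH3T3 monoculture, so mouse RNA added to its counts. Of the mitochondrial genes, MT-ND3, MT-RNR1, MT-ND1, MT-ND2 and MT-ATP6 had log2 changes of −3.45, −3.03, −3.00, −2.72 and −2.49 (edgeR adjusted p from 2.53e-07 for MT-ND1 to 0.0273 for MT-ND3). MT-ND3 lost its call in 8 of 14 settings, with the highest value without the first HA IP (0.535). MT-RNR1 did not pass without the first V5 IP (edgeR adjusted p = 0.0760), nor MT-ND1 and MT-ATP6 without the second (0.0824 and 0.133). The count of 23 was 59 without the first HA IP, with the balance turned to 42 higher and 17 lower, 52 without the first V5 IP and 117 without the second V5 IP, and of the 12 mitochondrial genes that fell 4 and 3 were called without these V5 IPs.

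Camera called 3 lists in HA against V5. The median log2 change over all 6244 human genes was 0.37 there, and members above or below 0 are to be read relative to it. The mitochondrially encoded genes had 10 of 13 that fell over all genes and 13 adjusted over the list alone (adjusted p = 2.01e-27, and 0.840 with an estimated correlation). All 7 immediate early genes lay below 0, with a median of −1.65 and none called either way (adjusted p = 0.0264, and 0.840 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had 42 of 48 above 0, with a median of 0.79 and none called either way (adjusted p = 8.52e-04, and 0.840 with an estimated correlation). With the GC trend removed the last 2 lists were not called (adjusted p = 0.0594 and 0.147), and translation factors were, downward (0.0311).

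Mouse RNA in the V5 IPs was compared with that in the HA IPs. Of 8221 genes, 2 rose and 20 fell in V5, and 11 of those that fell were mitochondrial, at a median of 8.36-fold over all 12. A pair of other genes was far higher in the HA IPs than in the V5 IPs. ENSMUSG00000043909.16 on chromosome 2 had 192 and 163 counts in the HA IPs and 1 and 0 in the V5 IPs, a ratio of 2288 (408 to 90640; edgeR adjusted p = 5.73e-11). ENSMUSG00000031955.10 on chromosome 8 had 788 and 2121 counts in the HA IPs and 92 and 21 in the V5 IPs (log2 −7.33, SE 0.56; edgeR adjusted p = 4.27e-10). Both kept their calls in each of 13 settings. The count of 22 was 435 without the first HA IP (257 higher and 178 lower in V5) and 794 without the second (568 and 226), which turned the balance, 2 without the first V5 IP and 3 without the second.

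**Figure D3:**
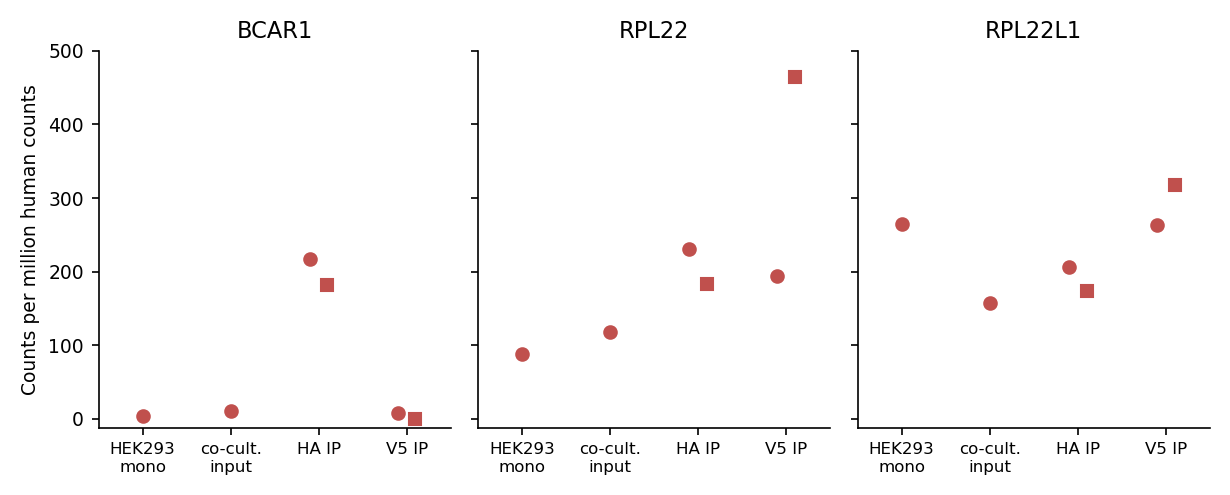
CPM of human counts of BCAR1, RPL22 and RPL22L1 in the HEK293 monoculture, the co-culture input and the IPs; circles are single libraries or first IPs and squares second IPs. BCAR1 is at 217 and 182 in the HA IPs and at 10.7 or less in the other libraries shown.

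HA IPs from the mixed culture were compared with the HEK293 monoculture, to see how far the recovered RNA resembled that of the pure line. Mitochondrial transcripts and MALAT1 were lower in the IPs, while BCAR1, MIF and NME2 were higher. Of 6244 genes, 3 rose and 20 fell, and 15 of the 17 mitochondrial genes were among those that fell. The large mitochondrial ribosomal RNA MT-RNR2 was at 2240 ± 773 CPM in the HA IPs (SD, n = 2) and 54816 CPM in HEK293 (log2 −4.61, SE 0.44; edgeR adjusted p = 2.72e-22). MT-ND4L, MT-RNR1, MT-ND3, MT-ND1, MT-ND4, MT-CYB and MT-CO3 had log2 changes of −5.86, −5.75, −5.23, −4.71, −4.28, −4.21 and −4.02 (edgeR adjusted p at most 3.66e-06, for MT-ND3, which did not pass without the first HA IP, 0.0748). MALAT1, a long RNA held in the nucleus, was at 403 ± 158 against 3107 CPM (log2 −2.95, SE 0.52; edgeR adjusted p = 6.28e-06). It was already at 269 CPM in the co-culture input, from which the HA IPs differed by 0.59 (SE 0.57; edgeR adjusted p = 0.853).

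Among the genes that rose, MIF, a cytokine (chromosome 22, 23894004 to 23895227), was at 497 ± 219 CPM in the HA IPs and 15.5 CPM in HEK293 (log2 4.98, SE 0.88; edgeR adjusted p = 5.77e-06). NME2, a nucleoside diphosphate kinase, was at 872 ± 383 and 59.5 CPM (log2 3.87, SE 0.72; edgeR adjusted p = 3.62e-05). Exons of other annotated genes covered 62.0% of the exonic bases of MIF and 22.9% of those of NME2, and reads were counted without strand, so counts of both are uncertain. They were already at 433 and 862 CPM in the co-culture input. BCAR1 had a ratio of 54.9 (18.7 to 268; edgeR adjusted p = 0.00399) and lost its call without the first HA IP (0.320) or the second (0.952). EIF2S3, a subunit of eIF2, fell by 2.63 (SE 0.70; edgeR adjusted p = 0.0448) and lost its call in 6 of 13 settings, among them without the first HA IP (0.0656) and without the second (1.00). The count of 23 was 63 without the first HA IP, with the balance turned to 42 higher and 21 lower, 50 without the first V5 IP and 48 without the second.

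Camera called 3 lists in HA against HEK293, all downward. The 13 mitochondrially encoded genes all fell, over all genes and adjusted over the list alone, with a median of −3.90 (adjusted p = 2.00e-41, and 0.321 with an estimated correlation). All 5 nuclear non-coding RNAs lay below 0, with 1 that fell over all genes and 2 adjusted over the list alone (adjusted p = 1.69e-07, and 0.321 with an estimated correlation). DNA replication had 9 above and 19 below and none called either way (adjusted p = 0.0404, and 0.813 with an estimated correlation). Replication-dependent histones lay above 0 in 12 of 14 and were not called (adjusted p = 0.0590).

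V5 IPs against the NIH3T3 monoculture asked the same of the mouse line. Of 8221 mouse genes, 2 rose and 29 fell, and 10 of the 12 mitochondrial genes were among those that fell, at a median of 11.6-fold over all 12. A gene on chromosome 17 was at 11.2 ± 1.81 CPM in the V5 IPs (SD, n = 2) and 2802 CPM in NIH3T3 (log2 −7.95, SE 0.51; edgeR adjusted p = 1.20e-11). It was already at 70.4 CPM in the co-culture input, so most of this difference lay between the input and NIH3T3. The count of 31 was 648 without the first HA IP, 628 without the second, 4 without the first V5 IP and 10 without the second, with 3 and 5 mitochondrial genes among them.

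The co-culture input was set beside the HEK293 monoculture to see how human RNA of the mixed culture differed from that of the pure line. With 1 library against 1 the differences had no replicate check and no p-value. Of 2584 human genes with at least 50 CPM in either library, 1390 differed at least 2-fold, 419 higher and 971 lower in the co-culture. Among the higher genes, MIF, NME2, KRTCAP2, NDUFA13 and RPS10 had log2 ratios of 4.24, 3.52, 2.98, 2.98 and 2.97, and exons of other genes covered from 18.4% (KRTCAP2) to 62.0% (MIF) of their exonic bases. TNR had a ratio of 58.4 (26.1 to 162), with counts also seen in NIH3T3 cells, and the log2 ratios of AL450405.1 and AL391244.1 were 3.08 and 2.97. Among the lower genes, 0 counts were found in the co-culture for SNW1, at least 8.80-fold lower, for RIDA (at least 9.04-fold), CLINT1 (8.45), KYAT3 (7.97), CCNG1 and ING3 (7.73 each) and UTP3 (7.49). Exons of other genes covered 20.3% of the exonic bases of KYAT3. NOP58, a protein of snoRNA complexes, had 2 against 210 counts, 37.5-fold lower (10.2 to 311).

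Lists of that comparison were placed among 10000 random lists matched on size and mean expression, as a description of these libraries. Translation factors had a median log2 ratio of −1.17, at the percentile 0.08, with 16 of 29 at least 2-fold lower, among them EIF5B (2 counts in the co-culture, 24.8-fold lower, 6.74 to 207), EIF2S3 (−3.70) and EIF3E (−3.64). Heat shock genes had a median of −1.31 (percentile 0.76), with 7 of 10 at least 2-fold lower, among them HSP90AA1 (−3.07) and DNAJA1 (−2.51). Proteasome genes had a median of −0.70 (percentile 3.40), with 12 of 28 at least 2-fold lower, among them PSMD14 (−3.29) and PSMA4 (−2.74). Ribosomal proteins had a median of −0.40 (percentile 0.01) and ER chaperones one of −0.85 (percentile 4.74). Medians were −0.20 for nuclear-encoded oxidative phosphorylation (percentile 5.14), −0.16 for mitochondrially encoded genes (25.7), −0.15 for snoRNA hosts (54.8), 0.59 for ATF4 genes (96.5), 0.71 for histones (89.2) and 0.28 for glycolysis and hypoxia (75.3). They were −0.51 for cholesterol synthesis (51.4), −0.63 for mitosis (26.6) and −0.61 for DNA replication (60.8), and the remaining lists had fewer than 5 members. With the GC trend removed, ribosomal proteins moved to a median of 0.15 (percentile 79.5) and mitochondrially encoded genes to 0.93 (99.98), snoRNA hosts to 0.90 (99.57), nuclear-encoded oxidative phosphorylation to 0.36 (97.47) and ER chaperones to −0.05 (24.1), while translation factors (0.12), heat shock (0.16) and proteasome (0.18) stayed at low percentiles with smaller medians (−0.35, −0.68 and −0.38). With that trend removed 685 genes differed at least 2-fold, 326 higher and 359 lower.

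**Figure D4:**
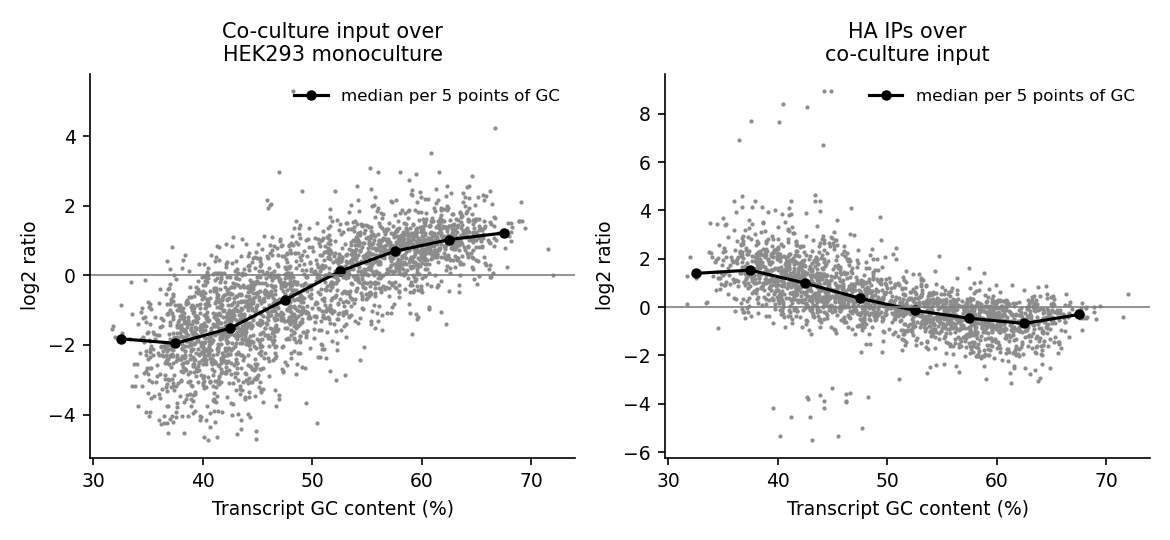
Log2 ratio against transcript GC content (percent) for human genes, of the co-culture input over the HEK293 monoculture and of the HA IPs over the co-culture input; grey points are genes and black points medians per 5 points of GC content with at least 20 genes. The ratio increases with GC content in the first (rho = 0.776) and decreases in the second (rho = −0.672).

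The co-culture input was also set beside the NIH3T3 monoculture for mouse genes. Of 2445 genes, 667 differed at least 2-fold, 276 higher and 391 lower in the co-culture, with a median log2 ratio of 0.04 over all genes. Of those at 2-fold 41.4% were higher, against 24.3% scaled by total counts and 55.6% (110 higher and 88 lower) at 200 CPM, so the balance depended on these choices. The mouse genes at 2-fold were 27.3% of those compared.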

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

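All tests of the pattern in this part were chosen after the result was seen. The mitochondrial share of the RNA of the untagged species differed between the antibodies in direction from the co-culture input. In the HA IPs the share of mouse counts lay 0.146 percentage points above the input (mean of 2 IPs), and in the V5 IPs the share of human counts lay −2.67 points from it. The mouse value rested mostly on the first HA IP, at 2.22% against 1.97% in the input, while the interval of the second (2.02%, 1.97 to 2.06%) overlapped that of the input, and the difference was not tested.

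RNA of the other species made up 17.9% and 22.4% of the counts in the HA IPs and 6.25% and 4.48% in the V5 IPs. Reads assigned to the wrong species are argued against, since the lowest of these shares was 175.2 times the highest in a monoculture, as is exchange of reads between libraries, since the lowest mouse share in an HA IP was 1367 times that in the HEK293 library. Mouse RNA in the HA IPs had a mitochondrial share at 108.3% of the way from the V5 IPs to the input (102.4 to 114.2), as lysate RNA carried along would have, but this share had been seen before. Across genes that RNA correlated less with the input (r = 0.699 and 0.803 for the first and second HA IP) than with the V5 IPs (0.793 to 0.895). This cannot decide either, since the 1 input library also correlated with the V5 IPs at only 0.845 and 0.852, against 0.957 between these. Human RNA in the V5 IPs lay at 48.29% (36.12 to 60.47), with 1 IP on either side of the middle, so carry-over and recovery of ribosomes cannot be told apart for either antibody. No biological explanation was tested.

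Counts of the absent species were found in both monocultures, which the comparisons used only as a background. In NIH3T3, 14 human genes had more than 3 counts, led by TNR with 160, which is 31.3% of the 511 human counts of that library. In HEK293, 6 mouse genes had more than 3 counts, and the highest had 12.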

How the results depend on the processing

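Of 135 summary values under alternative settings, 82 stayed within their error or within 1.5 times the reported count and 53 moved; most are counts or shares, which cannot change sign. Medians over genes did, among others with the GC trend removed from −0.39 to 0.03 for co-culture input against HEK293 and from 0.37 to −0.21 for HA against V5, and with total counts from 0.04 to −0.16 for mouse input against NIH3T3 and from 0.13 to −0.08 for mouse V5 against HA. For 161 named genes over 1516 settings, 1351 calls or values kept their side, 157 calls were lost, 8 values moved and 0 reversed; 5 named genes had no adjusted p in DESeq2 and are not counted there. Removing the GC trend and leaving out the co-culture input were chosen after seeing the data. The cause was not tested unless stated.

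The human share of the input, 26.9%, was 26.2% without mitochondrial genes, 25.6% without the 10 most abundant genes and 26.3% with genes of at least 100 counts. The first minus second IP difference was 4.72 against 4.55 points for HA without the 10 most abundant genes, and for V5 1.65 without them and 1.68 with genes of at least 100 counts, against 1.77.

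Over all genes, a filter of 50 counts in 2 libraries gave 4459 calls against 8554, with fewer genes tested, and 55.9% of calls were higher in HA against 41.0% with that filter, 75.2% with DESeq2 size factors, 69.8% with TMM and 49.6% without the first HA IP. For HA against input (39), DESeq2 size factors gave 68, total counts 104 (62.5% higher against 30.8%), DESeq2's test 64 and only the 2 groups compared 260. Total counts moved the median log2 change from 0.38 to 0.57 there and from 0.37 to 0.00 in HA against V5. For mouse V5 against input (67), DESeq2 gave 105 and only the 2 groups 896, and total counts turned the balance to 50 higher and 35 lower. For human HA against V5 (23), total counts gave 38 and removal of the GC trend 40. For mouse V5 against HA (22), the stricter filter gave 13 and only the 2 groups 12. For HA against HEK293 (23), total counts gave 53 (45.3% higher against 13.0%), DESeq2 39 and only the 2 groups 48. For mouse V5 against NIH3T3 (31), no filter gave 65, the stricter filter 11 and only the 2 groups 665. Camera with an estimated correlation called 0 lists in each human comparison, against 5, 3 and 3, but with 2 residual degrees of freedom it can hardly call any.

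IP order as a replicate block gave 112 calls for mouse V5 against input and 56 for mouse V5 against NIH3T3, and moved no other count over 1.5 times. Deviations of first and second IPs correlated at 0.20 in 2237 human and 0.35 in 2218 mouse genes, and with 2 pairs the order is not taken as a pairing.

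Genes at 2-fold between the co-culture input and HEK293 numbered 3591 at 10 CPM, 458 at 200 CPM and 685 with the GC trend removed, against 1390. For mouse they numbered 1918 and 198 at 10 and 200 CPM, against 667, since the minimum sets the genes compared.

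Leaving out 1 IP gave 72.2 to 76.8 points for the human share (74.5), 7150 to 7964 calls over all genes, 29 to 140 for HA against input, 1 to 867 for mouse V5 against input, 18 to 117 for human HA against V5, 2 to 794 for mouse V5 against HA, 26 to 63 for HA against HEK293 and 4 to 648 for mouse V5 against NIH3T3. The lone IP was assumed to vary like the other groups. The human counts of the V5 IPs, 128915 and 81798, limit what can be seen in human genes there.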

Other observations

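The tests of a mouse copy, of amplification, of 4-residue words, of co-culture, of length with GC content held and of removal of the GC trend were chosen after the result was seen.

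BCAR1 was recovered by the HA antibody, with 158 and 221 counts in the HA IPs and at most 3 in any other library. Its level in the NIH3T3 monoculture and V5 IPs reached at most 0.3428% of that in the lower HA IP. This cannot exclude reads of a mouse copy, since a mouse gene recovered by the HA antibody can be as scarce there. ENSMUSG00000043909.16 had 7 counts in NIH3T3 and 1 and 0 in the V5 IPs, against 192 and 163 in the HA IPs. ENSMUSG00000031955.10 was less scarce, with 178 counts in NIH3T3 and 92 and 21 in the V5 IPs, against 788 and 2121 in the HA IPs. Which mouse gene is the copy of BCAR1 was not looked up, since mouse identifiers had no symbols. Amplification of a few molecules in 1 library is argued against, since the lower HA count of BCAR1 was 158. The HA antibody may also bind the nascent BCAR1 protein: 4-residue words of the HA epitope occurred 8 times in its sequence, repeats counted, and in none of the other genes among 5846 tested as often (0.01711% of genes). A first search, set beforehand, for windows that share 5 of 9 residues with the epitope had left this open, since 1.3% of the genes had as many windows as BCAR1. The search for words was the second of 2 definitions, made after that outcome and with prior knowledge that BCAR1 carries repeats like YDVP, so it remains a hypothesis, and the mouse genes ENSMUSG00000043909.16 and ENSMUSG00000031955.10, which the HA antibody also recovered, could not be searched without mouse protein sequence.

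Of the human genes lower in HA than in V5 IPs outside mitochondria, MYH9, TRIP11, CIT, PRKDC, MYH10, IFFO1 and ONECUT2 were searched for the V5 epitope, with PRKDC, IFFO1 and ONECUT2 chosen after their values were seen. Their median best match of 5 residues equalled that of 95.1% of random sets matched on protein length and lay above that of 1.11%, so binding of the V5 antibody to these proteins cannot be told apart from chance by a score this coarse. Their transcripts were long, with a median of 8708 bases against 2881 over the genes tested. Across 2237 human genes the change of HA over V5 went weakly with transcript length (Spearman's rho = −0.2351). Length was not tested as an explanation here.

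Between the co-culture input and the HEK293 monoculture, 1390 human genes differed at least 2-fold. Sampling of fewer human reads in the input is argued against, since thinning the HEK293 counts to that depth left 1.3 genes at 2-fold (0 to 3 in 20 draws). Thinning repeats no library preparation, so spread between preparations at a low human content stays open. Transcript GC content may account for much of the difference: across genes its Spearman's rho with the log2 ratio was 0.7761. Genes at least 2-fold lower had a median GC content of 41.67% and those higher 60.13%. With the trend removed 685 genes were at 2-fold, and 434 of these had been among the 1390 in the same direction. Transcript length also met the bound set for it beforehand (rho = −0.3113), so it stays open, but little of it was left with GC content held (−0.03852). A change of the human cells in co-culture cannot be told apart from an effect of GC content. The 971 genes lower in the input had a median log2 ratio of −0.4007 in the HA IPs over HEK293, between the bounds set for either outcome. The 419 higher genes, which had no bound and no simulation, had one of 0.764. Both medians share the HEK293 library with the choice of the genes. In 20 simulations with no true difference the lower genes gave −0.6863 (−0.7704 to −0.5984). These gave every library the 51.2% spread of the fit, which rests partly on human RNA in the V5 IPs. They therefore cannot calibrate the observed value. The HA IPs followed GC content less over HEK293 (rho = 0.3232) than over the input (rho = −0.6719), which sets the input apart. Still, 1 input library cannot separate preparation from content.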
